A study of Homo sapiens and Mus musculus with 35 samples.

How the data were processed

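The material was cell-free plasma from people and mice, and the measurement was the abundance of small RNAs outside cells. Per the labels' protocols, RNA was extracted from 100 µl of plasma with Trizol LS, libraries were made with the Norgen Biotek small RNA kit, and reads were processed by the exceRpt small RNA-seq pipeline, version 4.6.2. The labels' protocol and the series' design text name different Illumina instruments, so the instrument is left open. The aligner settings, the genome build and the release of the miRNA, tRNA, piRNA and circRNA references were not given in the sources used here. The 35 libraries fell into 4 groups by their labels: 10 human controls, 10 human trauma samples, 6 sham mice and 9 mice with polytrauma, which means injury to several parts of the body. Nothing in the labels beyond separate sample titles says that each library came from a separate person or animal, and if some did not, the p-values measure only the spread between these samples.

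The deposited files held, for each library, 1 table each for mature miRNA, miRNA precursor, tRNA and piRNA, and 1 for circRNA in all but 7 mouse libraries. Per the file headers, each table gives a total read count per reference and an expected count adjusted for reads that map to several references, both made by the authors' pipeline and not normalized. The adjusted expected counts were rounded to whole numbers and used throughout, and the deposited total read count was an alternative. Identical values were found in 1 pair of files: the precursor table of mouse polytrauma library 4 equalled that of human control library 10. It holds 50 human and 0 mouse references, so it was left out in mouse, where class shares in polytrauma rest on 8 libraries, and kept in human. Whether it is that control's own file is not settled; without it human precursor reads rose by 0.374 on the log10 scale (exact permutation p = 0.0148). The 8 mouse circRNA tables held 1 to 18 reads each and were not analysed further. Mature miRNA tables also held 71 stem-loop references, at most 0.0045% of a library's reads, which were left out. References without a tRNA name took 0.34% to 9.07% of human tRNA reads and were left out. No 2 libraries of a group agreed within sampling noise, the lowest chi-square per degree of freedom being 289.

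Human libraries held 1312036 to 13740778 mature miRNA reads and mouse libraries 6689418 to 13654508. Data were simulated with the real means and library sizes, and with 1 common spread for all miRNAs of a species. The real fits let the spread differ between miRNAs, so recovery and false calls there may differ. In the simulated data the human test recovered 0 of 20 tested miRNAs changed 2-fold, 4 of 22 changed 4-fold and 21 of 24 changed 8-fold, with 2 calls among 343 unchanged miRNAs. The mouse test recovered 10 of 34, 29 of 41 and 37 of 38 at the same sizes, with 0 calls among 373 unchanged miRNAs. With no change simulated, both tests made 0 calls. The test of a difference between species recovered 74 of 118 tested 8-fold differences, with 2 calls among 98 unchanged miRNAs. In the list test, 1 of 20 unchanged simulations gave a call in each species, a list raised 4-fold was called in both, and in mouse 1 further list was called beside it. Simulated miRNAs varied independently of each other. In the real data the estimated correlation within lists ran from −0.0296 (mouse lymphocyte) to 0.656 (human red cell). These simulations therefore do not give the false-call rate of the list test in the real data. The permutation test gave p under 0.05 in 5.0% of 1000 unchanged simulations of 6 against 9 values. Reads carry no molecular identifiers, so counting intervals and floors cover counting error only.

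Each species was fitted alone with edgeR 4.0.16 in R 4.3.3: filterByExpr with its default minimum count of 10 and minimum total of 15, TMM factors, glmQLFit and a two-sided glmQLFTest, with Benjamini-Hochberg adjustment and a threshold of 0.05. The test left 348 of 1228 human and 473 of 1011 mouse miRNA features, which held 99.9% and 100.0% of the mature miRNA reads. A feature that joins miRNAs of identical sequence, such as miR-199a-3p/miR-199b-3p, was kept as 1 feature. Members of a family such as let-7 differ by few bases, so reads could be divided between them by the authors' counting. Abundance is given as counts per 1000000 mature miRNA reads after TMM scaling (CPM), as mean ± SD. Differences between the species were tested as the interaction of species and trauma over the 196 miRNAs that passed the filter in both, matched by name. The labels do not say whether the species were sequenced together, and a difference between runs would cancel only as far as it affects both arms of a species alike.

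In all, 16 lists of miRNAs were tested with camera in limma 3.58.1 at the preset correlation of 0.01, with the estimated correlation and fry beside it: liver, skeletal muscle and heart, brain, red cell, neutrophil and monocyte, lymphocyte, endothelium, smooth muscle and fibroblast, epithelium, pancreas, intestine and kidney, inflammation-responsive, reported ligands of TLR7 or TLR8, let-7 family, miR-17-92 and related clusters, and the imprinted DLK1-DIO3 cluster. The lists come from general knowledge of where these miRNAs are abundant; most miRNAs are made in several tissues, and some stand in more than 1 list. The haemolysis index was the log2 ratio of miR-451a, a red cell miRNA, to miR-23a-3p, with 0.5 counts added to each. Class shares, log10 class totals, the number of miRNAs detected and the index were compared by two-sided permutation tests of the difference in means, with 100000 resamples in human and exact enumeration in mouse (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1). These p-values were adjusted over 12 human and 10 mouse measures. That family had not been written down in advance: it was settled after the p-values were seen, and unadjusted values are therefore given too. Adjusted over the 2 haemolysis tests alone, the mouse index would pass. tRNA counts were scaled by TMM within tRNA and summed per anticodon in mouse; the human references name only the amino acid, so human counts were summed per amino acid, a departure from the plan. piRNA was scaled by the mature miRNA library size and factors, and circRNA by TMM within circRNA.

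Groups, tests, lists, the rule for naming miRNAs and the first set of alternatives were fixed before the data were examined. The rule named, per species and direction, the 6 called miRNAs of lowest adjusted p and the 5 further ones of highest mean CPM, the 3 most abundant tested members of each list, up to 6 miRNAs called in both species in the same direction and up to 6 in opposite directions, the 4 of lowest adjusted interaction p, and always miR-451a, miR-23a-3p and miR-122-5p. For tRNA it named up to 3 features per direction and for piRNA up to 2. Any other miRNA named was chosen after its values were seen. Genomic positions of hairpins were taken by name from GENCODE release 29 on GRCh38, where 15 of 15 hairpins matched; the authors' own build was not given. Alternatives covered normalization (RLE, upper-quartile, total count, DESeq2 1.42.0), low-count filters, the read count column, thinning to the smallest library, covariates for haemolysis and depth, removal of the red cell list, a replicate block, a fold threshold and leaving out each library. Fits limited to libraries of 3000000 to 9000000 reads, the depth covariate and leave-one-out fits for lists, fits with 4 or 6 of the trauma libraries, the mouse libraries of the block without the block, and the count of miRNAs in equal numbers of reads were added after seeing the data.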

Results

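Small RNA outside cells was counted in plasma of 10 human controls and 10 trauma patients, and of 6 sham mice and 9 mice with polytrauma. Mature miRNA reads per library ranged from 1312036 to 11401091 in human controls (median 3356756) and from 1321659 to 13740778 in human trauma (median 7152022). They ranged from 6689418 to 11732262 in sham mice (median 8427716) and from 8459470 to 13654508 in polytrauma (median 11689715). Depth differed between the human groups, by 0.321 on the log10 scale (permutation p = 0.0230, adjusted p = 0.0307), and low-abundance miRNAs are measured less precisely in the shallower controls. The comparisons ask which plasma small RNAs differ after injury, in people and in a mouse model, and whether the differences are shared.

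In human plasma, miRNAs known from smooth muscle and fibroblasts were far more abundant after trauma. miR-143-3p, abundant in smooth muscle, rose 27.99-fold, from 2689 ± 894 to 75278 ± 47037 counts per 1000000 mature miRNA reads (CPM, mean ± SD, n = 10 and 10), a log2 fold change of 4.81 (SE 0.435, adjusted p = 1.87e-09). miR-145-3p, from the same cluster, rose 14.5-fold (log2 fold change 3.86, SE 0.403, adjusted p = 1.74e-08), and miR-199a-3p/miR-199b-3p, abundant in fibroblasts, rose 24.3-fold (SE 0.453 on the log2 scale, adjusted p = 7.00e-09). For each of these 3 features, every trauma library lay above every control library. The rise was smaller in trauma libraries 6 to 9. There the median log2 fold change of the whole list was 2.27, against 3.91 in the other 6, and the haemolysis index was higher. Among the miRNAs that fell, miR-150-5p, abundant in mature lymphocytes, was 3.46-fold lower, at 87.2 ± 40.8 against 301 ± 92.0 CPM (log2 fold change −1.79, SE 0.396, adjusted p = 0.00148), again without overlap between the groups.

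Of 348 miRNA features tested in human plasma, 54 rose and 16 fell in trauma (edgeR quasi-likelihood test, adjusted p under 0.05), and 112 had an unadjusted p under 0.05. The groups did not overlap at all in 14 of the 348, where chance gives 0.00108% per feature. miR-30a-5p rose 9.41-fold (log2 fold change 3.23, SE 0.420, adjusted p = 1.38e-06), miR-224-5p 7.98-fold (3.00, SE 0.423, adjusted p = 5.50e-06) and miR-10a-5p, encoded in the HOXB cluster, 6.77-fold (2.76, SE 0.402, adjusted p = 8.18e-06). Abundant miRNAs that rose included miR-192-5p, to 39495 ± 42567 CPM from 12819 ± 6447, miR-125a-5p (log2 fold change 2.15), miR-99a-5p (1.82), miR-100-5p (1.72) and miR-10b-5p (1.08). Each was above the control median in 8 or 9 of 10 trauma libraries. Those that fell included miR-423-5p, from 68205 ± 40090.4 to 23352 ± 10371 CPM (log2 fold change −1.55, SE 0.365, adjusted p = 0.00256), miR-877-5p (−1.51, SE 0.340, adjusted p = 0.00177) and miR-4433b-5p (−4.49, SE 0.818, adjusted p = 0.000168), each below the control median in 10 of 10 libraries. miR-483-5p, encoded within the IGF2 gene, had a log2 fold change of −2.61, miR-6803-3p −5.19, miR-4732-3p −1.88, miR-215-5p −1.69, miR-320b −1.64, miR-2110 −1.47 and miR-30c-5p −0.97.

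The number of calls depended on depth and on the haemolysis index. With every library thinned to the smallest total, 34 human miRNAs rose and 28 fell, and 48 of the 70 calls were kept. With the log2 depth as a covariate 29 rose and 8 fell, and 35 were kept. With the haemolysis index as a covariate 10 rose and 8 fell, and 18 were kept. Of the named miRNAs that were called, 19 of 36 lost the call with the haemolysis index and 17 of 37 with depth. Calls split 77.1% higher under TMM, 62.5% under DESeq2 and 69.9% under RLE factors.

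The hairpins of the leading miRNAs are placed as follows in GENCODE release 29 on GRCh38. MIR143 lies on chromosome 5 at 149428918 to 149429023 within an exon of at least 1 transcript of the noncoding gene CARMN, and MIR145 at 149430646 to 149430733 within a CARMN intron. MIR214 (chromosome 1, 172138798 to 172138907) lies within an exon of DNM3OS, antisense to DNM3, and the hairpin of miR-199a at 172144535 to 172144644 overlaps an exon of the same gene; the feature miR-199a-3p/miR-199b-3p has further hairpins on chromosomes 19 and 9. MIR30A (chromosome 6, 71403551 to 71403621) is intronic in LINC00472, MIR224 (chromosome X, 151958578 to 151958658) lies within an exon of GABRE, and MIR10A (chromosome 17, 48579838 to 48579947) within a HOXB3 intron and a HOXB4 exon. Among the miRNAs that fell, MIR150 (chromosome 19, 49500785 to 49500868) lies in no gene on its strand, MIR423 (chromosome 17, 30117079 to 30117172) within an exon of NSRP1 and MIR877 (chromosome 6, 30584332 to 30584417) within an intron of ABCF1.

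By list, all 8 tested members of the smooth muscle and fibroblast list rose, with a median log2 fold change of 3.50 (range 2.39 to 5.36). When adjusted over the list alone 8 also passed. The 5.36 belongs to miR-214-3p (SE 0.967). This miRNA, miR-145-5p and miR-199b-5p had no reads in some control libraries, so the size of their folds is uncertain. The list was higher than other miRNAs by camera (adjusted p = 6.25e-06), but adjusted p = 0.123 with an estimated correlation. The trauma group was not uniform: for all 8 members, libraries 6 to 9 lay below every other trauma library (miR-143-3p at 14.49 to 14.99 against 16.03 to 17.19 on the log2 CPM scale), and for 6 of the 8 they still lay above every control. Of the 348 miRNAs, 101 did not overlap between these 4 libraries and the other 6. This was the most of 456 ways to set 3 to 5 trauma libraries apart, where the median was 1. Among controls the most was 22. With libraries 6 to 9 alone against controls, 8 miRNAs rose and 2 fell, and 10 of the 70 calls were kept. With the other 6 alone, 73 rose and 41 fell, and 66 were kept. Fewer libraries also give less power. The haemolysis index moved with the same groups, at 8.00 ± 0.612 in controls and 5.85 ± 1.97 in trauma (permutation p = 0.00646, adjusted p = 0.0155, lower than the control median in 9 of 10 libraries). It was 6.98 to 9.42 in trauma libraries 6 to 9, near the 7.16 to 9.21 of controls, and 3.60 to 5.59 in the other 6. With the index as a covariate 4 of the 8 members passed, with a median of 2.35. In the red cell list none of 8 members passed, and 0 when adjusted over the list alone; miR-486-5p, the most abundant, was at 496608 ± 203036 CPM in controls and 192276 ± 168211 in trauma (log2 fold change −1.37, adjusted p = 0.0593), miR-451a had −0.73 (adjusted p = 0.246) and miR-92a-3p −0.85 (adjusted p = 0.0676). The list as a whole stood lower than other miRNAs by camera (median −0.74, adjusted p = 0.00170, but adjusted p = 0.495 with an estimated correlation). It lost that call with trauma libraries 6 to 9 alone and with the haemolysis covariate. Its members took 50.4% to 74.0% of reads in controls, 47.8% to 62.4% in trauma libraries 6 to 9 and 2.11% to 22.6% in the other 6. miR-23a-3p, the other part of the index, itself rose (log2 fold change 1.10, SE 0.308, adjusted p = 0.00901).

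**Figure D1:**
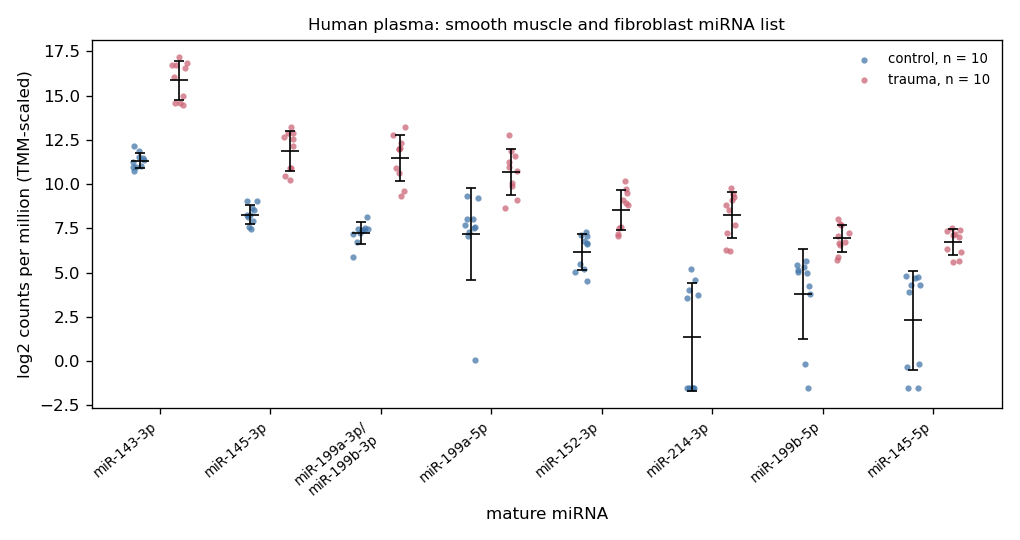
Abundance of the 8 tested members of the smooth muscle and fibroblast list in human plasma, as log2 CPM after TMM scaling, with 1 point per library (10 controls, 10 trauma) and bars for the mean ± SD. miR-143-3p lay between 10.74 and 12.17 in controls and between 14.49 and 17.19 in trauma. Points at −1.50, in controls of miR-214-3p, miR-199b-5p and miR-145-5p, are libraries without reads of that miRNA.

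Of the 4 brain list members tested, miR-132-3p and miR-383-5p rose and 0 fell (2 when adjusted over the list alone), while miR-128-3p (log2 fold change 0.29) and miR-323a-3p (1.67) did not pass. miR-132-3p is also induced by inflammation and is not specific to neurons; it had 1 read over all controls and 924 over trauma libraries, a ratio of 465.7 with a 95% counting interval of 83.4 to 18410. miR-383-5p had 35 control reads, all in 1 library, against 1614. The brain list passed camera (adjusted p = 0.0141, but adjusted p = 0.123 with an estimated correlation) and was lost on thinning (adjusted p = 0.639) and without trauma library 9, the shallowest of its group (adjusted p = 0.0502). In the endothelium list 4 of 7 rose (7 when adjusted over the list alone), among them miR-10a-5p and miR-10b-5p, while miR-126-3p, the most characteristic endothelial miRNA, had 0.74 (adjusted p = 0.106). That list passed camera at adjusted p = 0.0336, but adjusted p = 0.495 with an estimated correlation, and 0.165 with the haemolysis covariate. Leaving out control library 1, 8 or 9 or trauma library 9 also ended that call, at adjusted p = 0.0785, 0.0668, 0.0885 and 0.0610.

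The remaining 12 human lists did not pass camera. In the liver list 3 of 8 rose (5 when adjusted over the list alone; camera adjusted p = 0.238), including miR-192-5p and miR-148a-3p, while miR-122-5p, the main hepatocyte miRNA, was at 218969 ± 265319 CPM in trauma and 78884 ± 65334 in controls (log2 fold change 1.47, adjusted p = 0.0949), and miR-101-3p had 0.88. In the skeletal muscle and heart list 1 of 4 rose (1 over the list alone; adjusted p = 0.0988): miR-1-3p, by 7.12-fold, while miR-206 (1.05) and miR-133a-3p (0.60) did not pass. In the epithelium list miR-200a-3p, miR-200b-3p and miR-141-3p, all of the miR-200 family, rose with log2 fold changes of 3.77, 3.73 and 3.79, 3 of 5 members tested (4 when adjusted over the list alone; camera adjusted p = 0.0646). The imprinted DLK1-DIO3 cluster had 2 of 21 higher (2 over the list alone; adjusted p = 0.141), among them miR-654-3p (2.46), while miR-127-3p (0.56) and miR-409-3p (−0.06) did not pass.

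Among lists of blood cells, the lymphocyte list had 1 of 8 lower, miR-150-5p, with miR-181a-5p at 0.04 and miR-342-3p at −0.05 (1 over the list alone; camera adjusted p = 0.238). In the neutrophil and monocyte list none of 3 passed (0 over the list alone; adjusted p = 0.647), with miR-223-3p at 0.78, miR-223-5p at 1.05 and miR-142-5p at 0.30. Of 10 inflammation-responsive miRNAs 3 rose (3 over the list alone; adjusted p = 0.637), miR-125a-5p, miR-99b-5p and miR-132-3p, while miR-146a-5p had 0.73 (adjusted p = 0.0908). Of 11 reported TLR7 or TLR8 ligands 3 rose (3 over the list alone; adjusted p = 0.647). In the let-7 family 1 of 9 rose, let-7c-5p (2.35), with let-7b-5p at −0.52, let-7f-5p at −0.53 and let-7i-5p near 0 (1 over the list alone; adjusted p = 0.271). The miR-17-92 and related clusters had 0 of 10 called (0 over the list alone; adjusted p = 0.397), with miR-25-3p at 0.03 and miR-363-3p at −0.74. The pancreas list had 1 of 2 higher, miR-148a-3p (2.91), with miR-375-3p at 0.13 (1 over the list alone; adjusted p = 0.637). In the intestine and kidney list miR-192-5p and miR-30a-5p rose while miR-215-5p and miR-30c-5p fell, of 6 tested (2 and 2 over the list alone; adjusted p = 0.790). For that list camera's direction was lower while the median was 1.02 and the mean 0.71, and for the let-7 family camera and the median (−0.00) were lower while the mean was 0.15. By fry, which asks only whether a list moves on balance in 1 direction, 11 of the 16 human lists passed.

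In mouse plasma, 7 of the 9 tested members of the let-7 family were more abundant after polytrauma. let-7f-5p rose 5.43-fold, from 303 ± 80.1 to 1645 ± 515 CPM (n = 6 and 9; log2 fold change 2.44, SE 0.289, edgeR adjusted p = 1.66e-06), let-7d-5p 9.39-fold (3.23, SE 0.385, adjusted p = 1.66e-06) and let-7i-5p 8.37-fold (3.06, SE 0.366, adjusted p = 1.66e-06), each without overlap between the groups. miR-451a, the red cell miRNA, also rose, 3.59-fold (log2 fold change 1.85, SE 0.303, adjusted p = 8.22e-05). miR-205-5p, known from stratified epithelium, fell from 1042 ± 376 to 186 ± 31.3 CPM, 5.60-fold (log2 fold change −2.49, SE 0.233, adjusted p = 8.99e-08). miR-125b-5p fell 3.44-fold, from 23680 ± 5710.2 to 6893 ± 3203 CPM (log2 fold change −1.78, SE 0.300, adjusted p = 9.93e-05).

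Of 473 mouse features tested, 65 rose and 55 fell, and 166 had an unadjusted p under 0.05. The groups did not overlap in 46 of the 473, where chance gives 0.0400% per feature. let-7c-5p (log2 fold change 2.26), miR-106b-3p (2.56) and miR-3535 (3.14) completed the 6 strongest increases by adjusted p. Among abundant miRNAs, miR-192-5p rose to 53870 ± 26921 CPM from 24799 ± 8389 (log2 fold change 1.12, SE 0.354, adjusted p = 0.0215), and miR-215-5p (1.17), miR-25-3p (1.86), miR-145a-5p (1.76) and miR-145a-3p (1.62) rose too. By adjusted p, and not by size of the fold, the strongest decreases after miR-205-5p were miR-877-5p (−2.47, SE 0.292, adjusted p = 1.66e-06), miR-149-5p (−1.90), miR-511-5p (−2.03) and miR-322-3p (−1.33). Abundant miRNAs that fell were miR-10b-5p, from 80269 ± 18761 to 41091 ± 17257 CPM (−0.97, SE 0.295, adjusted p = 0.0175), miR-125a-5p (−1.71), miR-423-5p (−1.05), miR-146b-5p (−0.83) and miR-191-5p (−0.78), each below the sham median in 9 of 9 polytrauma libraries. With depth as a covariate 36 rose and 34 fell and 69 of the 120 calls were kept. With the haemolysis index 46 rose and 34 fell and 78 were kept. Calls were 54.2% higher under TMM, and 44.6% under total counts.

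**Figure D2:**
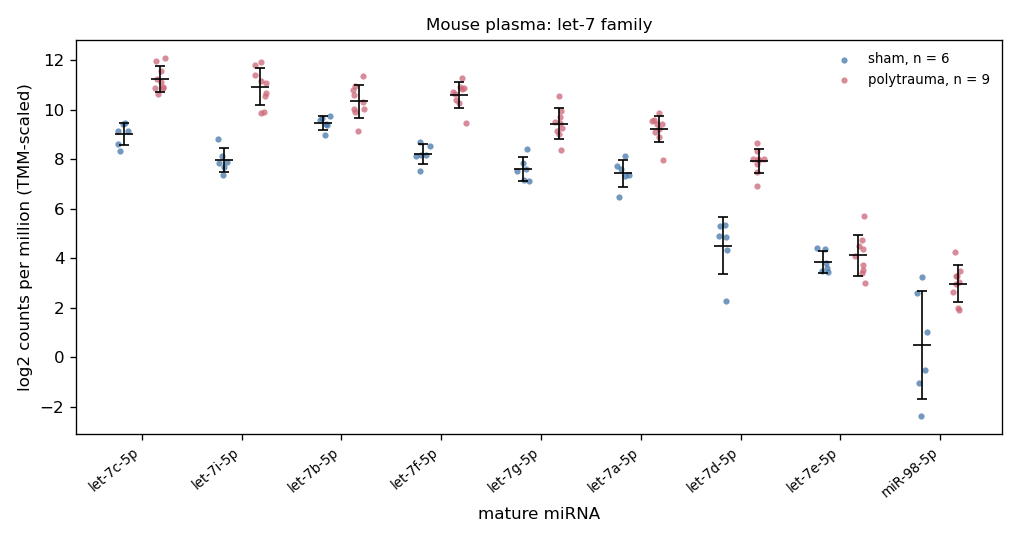
Abundance of the 9 let-7 family members tested in mouse plasma, as log2 CPM after TMM scaling, with 1 point per library (6 sham, 9 polytrauma) and bars for the mean ± SD. let-7f-5p lay between 7.52 and 8.70 in sham and between 9.47 and 11.31 in polytrauma, while let-7e-5p and miR-98-5p did not pass the test.

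The let-7 family was the one mouse list of 16 that passed camera: 7 of 9 members rose, 7 also when adjusted over the list alone, and the median log2 fold change was 1.88 (adjusted p = 4.86e-05, but adjusted p = 0.392 with an estimated correlation). let-7b-5p rose least of the 7 (0.98). In the red cell list 4 of 10 rose (5 when adjusted over the list alone; camera adjusted p = 0.0685), miR-451a, miR-144-3p, miR-144-5p and miR-16-5p, while the most abundant, miR-486a-5p/miR-486b-5p, had 0.31 (adjusted p = 0.569) and miR-92a-3p −0.09. The haemolysis index was −1.46 ± 0.256 in sham and −0.87 ± 0.696 in polytrauma (exact permutation p = 0.0484, adjusted p = 0.0967), above the sham median in 7 of 9. Adjusted over the 10 mouse measures it did not pass, and that choice of family decides the call. miR-23a-3p, its other part, itself rose (log2 fold change 1.35, adjusted p = 0.00494), which holds the index down. Of the 12 reported TLR7 or TLR8 ligands 6 rose (6 over the list alone; adjusted p = 0.0685), 3 of them let-7 members, while miR-29a-3p had 0.74 (adjusted p = 0.133). In the miR-17-92 and related clusters 3 of 10 rose (3 over the list alone; adjusted p = 0.119), miR-25-3p, miR-93-5p (1.46) and miR-20a-5p.

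Among mouse tissue lists, 5 of 7 liver members rose (5 over the list alone; camera adjusted p = 0.262), including miR-148a-3p (1.63), whereas miR-122-5p had −0.01 (SE 0.651, adjusted p = 0.989), with 8 of 9 polytrauma libraries below the sham median and 1 far above it. In the skeletal muscle and heart list 1 of 6 rose (1 over the list alone; adjusted p = 0.894), the skeletal muscle miRNA miR-206-3p by 2.81-fold, with miR-1a-3p at 0.86 and miR-133a-3p at −0.48. In the intestine and kidney list 3 of 8 rose and 1 fell (3 and 1 over the list alone; adjusted p = 0.713), with miR-30a-5p at 0.42. In the pancreas list miR-217-5p, abundant in acinar cells, rose 7.00-fold (log2 fold change 2.81, SE 0.833, adjusted p = 0.0145), and miR-148a-3p rose, 2 of 5 (2 over the list alone; adjusted p = 0.582), with miR-375-3p, the islet miRNA, at 0.74. In the epithelium list 3 of 8 rose, including miR-200a-3p (1.41), and miR-205-5p fell (3 and 1 over the list alone; adjusted p = 0.984), with miR-200b-3p at −0.08. The median of that list, 0.70, includes miR-31-5p, which had 0 reads over all sham libraries and 226 over polytrauma, at least 39.6-fold higher against a floor of 3 counts over the group; its place above the median is the same at that bound. In the smooth muscle and fibroblast list miR-145a-5p and miR-145a-3p rose and miR-214-3p fell, of 8 (2 and 1 over the list alone; adjusted p = 0.986), with miR-143-3p at 0.07.

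The remaining mouse lists did not pass camera. The endothelium list had 2 of 6 lower, among them miR-10b-5p (2 over the list alone; camera adjusted p = 0.293), with miR-10a-5p at 0.40 and miR-126a-3p at −0.16. The brain list had 1 of 10 higher, miR-132-3p (1.37), and 1 lower, miR-124-3p (−2.04), the same when adjusted over the list alone (adjusted p = 0.906), with miR-128-3p at 0.37 and miR-323-3p at 0.06. Of 11 inflammation-responsive miRNAs 1 rose and 2 fell (1 and 2 over the list alone; adjusted p = 0.582), with miR-146a-5p at 0.24 and miR-99b-5p at −0.28. The neutrophil and monocyte list had 1 of 3 lower, miR-223-3p (−0.85, SE 0.292, adjusted p = 0.0335), with miR-223-5p at 0.58 and miR-142a-5p at 0.09 (1 over the list alone; adjusted p = 0.894). The lymphocyte list had 1 of 7 higher (1 over the list alone; adjusted p = 0.986), with miR-150-5p at −0.50, miR-181a-5p at 0.48 and miR-342-3p at 0.47. In the imprinted DLK1-DIO3 cluster 5 of 21 fell, including miR-541-5p (−1.34) and miR-409-3p (−1.04), and 1 rose (5 and 1 over the list alone; adjusted p = 0.822), with miR-136-3p at 0.61. Camera's direction was lower for this cluster (median 0.34, mean 0.05), for smooth muscle and fibroblast (median 0.38, mean 0.33) and for neutrophil and monocyte (median 0.09, mean −0.06), against the sign of the median. By fry 7 of the 16 mouse lists passed.

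Of 196 miRNAs tested in both species, 46 had an effect that differed between species (edgeR interaction test, adjusted p under 0.05; 72 at an unadjusted p under 0.05), 29 with the human effect above and 17 with the mouse effect above. The mouse effect minus the human effect on the log2 scale was −4.76 for miR-199a-3p/miR-199b-3p (SE 0.481, adjusted p = 5.18e-10), −4.53 for miR-143-3p (SE 0.484, adjusted p = 1.33e-09) and −3.48 for miR-224-5p (SE 0.478, adjusted p = 4.96e-07). For miR-132-3p, which rose in both, it was −7.15 (adjusted p = 1.35e-06), a fitted value that rests on 1 human control read and sets no bound. Matching by name leaves out pairs such as human miR-145-3p (3.86) and mouse miR-145a-3p (1.62), which both rose. The 2 comparisons differ in more than species, with trauma over controls in human and polytrauma over sham in mouse. Mean haemolysis index was 8.00 in human controls and 5.85 in trauma, but −1.46 in sham mice and −0.87 in polytrauma. These differences therefore cannot be put down to species alone.

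Of 196 miRNAs, 8 rose in both species, where independent lists would share 8.79 (Fisher's exact test, two-sided, p = 0.833, adjusted p = 1.00), among them let-7c-5p (log2 fold change 2.35 in human and 2.26 in mouse), miR-148a-3p (2.91 and 1.63), miR-141-3p (3.79 and 1.71) and miR-143-5p (2.65 and 1.68). Both species had lower miR-877-5p (−1.51 and −2.47) and miR-483-5p (−2.61 and −1.89); 4 fell in both against 1.11 by chance (exact p = 0.0129, adjusted p = 0.0517 over 4 overlaps). Called in opposite directions were miR-125a-5p, miR-125b-5p, miR-10b-5p, miR-214-3p and miR-29b-3p, higher in human and lower in mouse, against 6.64 by chance, and miR-215-5p, lower in human and higher in mouse, against 1.46 by chance. Across the 196 miRNAs, which are not independent replicates, the effects had Pearson's r = −0.0254 and Spearman's rho = −0.0034, and 53.1% had the same sign; 87 of 100 splits of the samples gave an r at least as far from 0.

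**Figure D3:**
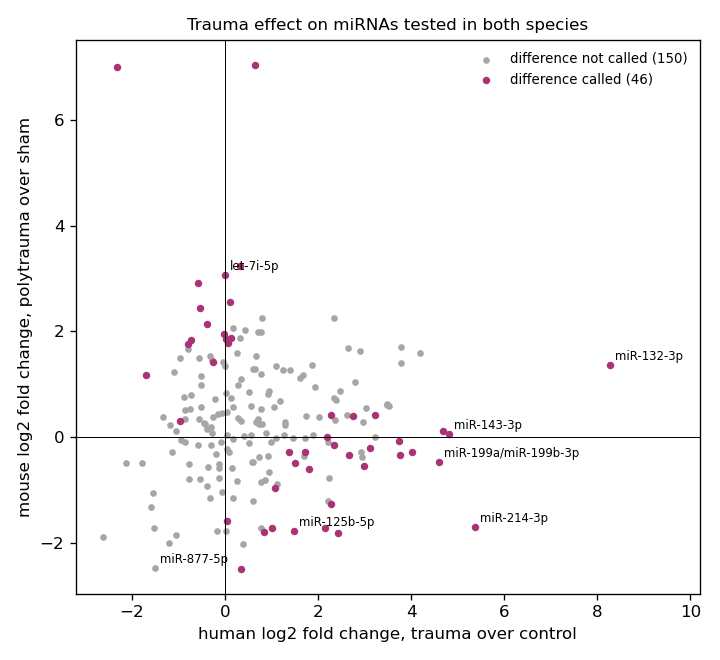
Log2 fold change in human (trauma over control, x axis) against mouse (polytrauma over sham, y axis) for the 196 miRNAs tested in both species, with 1 point per miRNA and the 46 whose effects differed by the interaction test in colour. miR-143-3p lies at 4.81 in human and 0.07 in mouse; points near 7 in mouse and 8 in human are miRNAs with 0 to 2 reads over the sham or control libraries, whose fitted values set no bound.

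The make-up of the counted small RNA differed in human plasma. Mature miRNA took 93.2% ± 3.79 of counted reads in controls and 97.6% ± 0.922 in trauma (n = 10 and 10, permutation p = 0.00154, adjusted p = 0.00924; higher than the control median in 10 of 10). The share of tRNA fell from 3.56% ± 3.53 to 0.610% ± 0.797 (p = 0.00308, adjusted p = 0.00924 by permutation, below the control median in 9 of 10). Without trauma library 9 the trauma mean was 0.365% ± 0.199 (exact permutation p = 0.000108). Without control library 8 the control mean was 2.62% ± 2.01 (exact permutation p = 0.00706). For piRNA the share fell from 2.24% ± 2.02 to 0.579% ± 0.331 (permutation p = 0.00242, adjusted p = 0.00924, 10 of 10). That fall rested mainly on 1 reference, piR-33043, at 21920 ± 19640 CPM of miRNA reads in controls and 637 ± 724 in trauma. The next most abundant tested reference in controls, piR-34736, rose instead, from 543 ± 826 to 4981 ± 4395 CPM. tRNA reads fell by 0.468 on the log10 scale (permutation p = 0.00940, adjusted p = 0.0161) while mature miRNA, precursor and circRNA reads rose by 0.321, 0.405 and 0.260 (p = 0.0230, 0.00790 and 0.0120, adjusted p = 0.0307, 0.0158 and 0.0179 by permutation). piRNA reads differed by −0.222 (p = 0.291, adjusted p = 0.317). The shares of precursor and circRNA did not differ past the threshold (permutation p = 0.142 and 0.759, adjusted p = 0.170 and 0.759). The number of miRNAs detected rose from 345 ± 85.5 to 631 ± 177 (permutation p = 0.000500, adjusted p = 0.00600), and from 334 ± 80.8 to 544 ± 125 in equal numbers of reads (permutation p = 0.000720). Equal totals did not leave equal reads for the less abundant miRNAs. The most abundant miRNA took 47.0% ± 8.64 of mature miRNA reads in controls and 31.8% ± 12.4 in trauma. The count therefore cannot separate more kinds of miRNA from a smaller share of the dominant one.

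**Figure D4:**
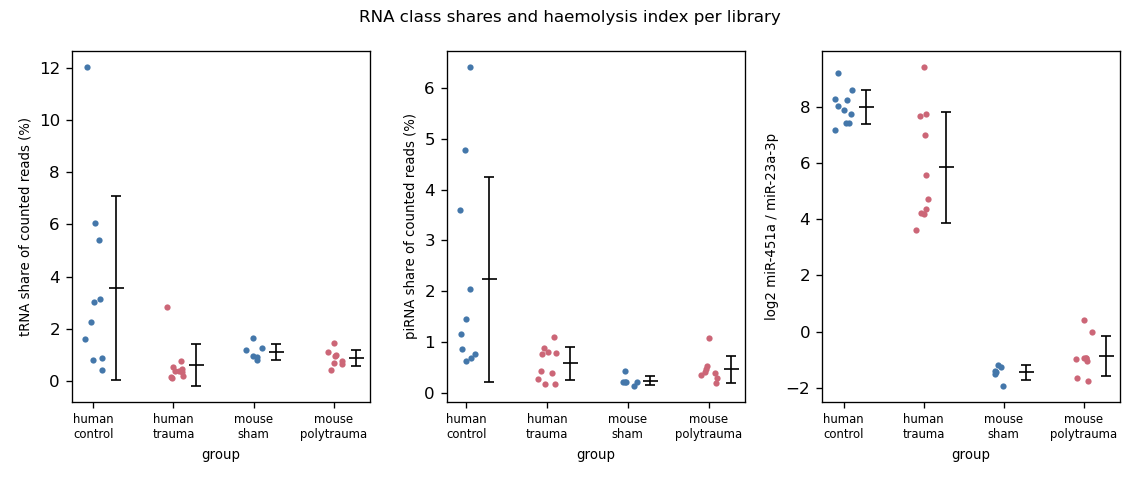
Shares of counted reads, in percent, taken by tRNA and by piRNA, and the haemolysis index (log2 of miR-451a over miR-23a-3p), per library, with bars for the mean ± SD. The shares are from 10 human controls, 10 human trauma, 6 sham, and 8 polytrauma, without library 4. The index is drawn for all 9 polytrauma libraries. In human plasma the tRNA share lay between 0.418% and 12.04% in controls and between 0.112% and 2.81% in trauma.

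In mouse plasma the shares of mature miRNA, precursor and tRNA did not differ past the threshold (exact permutation p = 0.284, 0.278 and 0.175, adjusted p = 0.315, 0.315 and 0.2502; n = 6 and 8). The piRNA share was 0.240% ± 0.0944 in sham and 0.463% ± 0.267 in polytrauma (exact permutation p = 0.0253, adjusted p = 0.0844; above the sham median in 7 of 8). piRNA reads rose by 0.392 on the log10 scale (exact permutation p = 0.00280, adjusted p = 0.0140; 9 of 9), and the number of miRNAs detected rose from 486 ± 59.2 to 600 ± 40.6 (exact permutation p = 0.00240, adjusted p = 0.0140; 9 of 9). Reads of mature miRNA, precursor and tRNA differed by 0.109, 0.193 and −0.0062 on the log10 scale (exact permutation p = 0.0360, 0.0666 and 0.932, adjusted p = 0.0899, 0.111 and 0.932).

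Within human tRNA, reads of tRNA-His rose 8.55-fold (log2 fold change 3.10, SE 0.478, edgeR adjusted p = 3.70e-05) and those of tRNA-Gln 5.74-fold (2.52, SE 0.430, adjusted p = 7.71e-05), tRNA-Ser rose (0.87, adjusted p = 0.00712) and tRNA-Asp fell 2.46-fold (−1.30, SE 0.276, adjusted p = 0.000845), of 23 tested. These are changes relative to other tRNA; scaled by the miRNA library, 0 rose and 6 fell. In mouse, 5 of 48 anticodons rose and 7 fell. Initiator methionine tRNA, tRNA-iMet-CAT, fell 12.02-fold (log2 fold change −3.59, SE 0.365, adjusted p = 4.65e-07), tRNA-Lys-TTT 2.56-fold (−1.36, SE 0.244, adjusted p = 0.000306) and tRNA-Thr-TGT 7.21-fold (−2.85, SE 0.574, adjusted p = 0.000919). tRNA-Val-CAC (1.20), tRNA-Val-AAC (1.26) and tRNA-Gly-GCC (0.77), the most abundant of the 3, rose; scaled by the miRNA library, 2 rose and 18 fell.

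Of 10 human piRNA references tested, 7 fell and 2 rose relative to miRNA. piR-33043 fell 34.4-fold, from 21920 ± 19640 to 637 ± 724 CPM of miRNA reads (log2 fold change −5.10, SE 0.727, edgeR adjusted p = 2.45e-07; 10 of 10 below the control median), and piR-33044 13.04-fold (−3.70, SE 0.604, adjusted p = 1.97e-06). piR-54381 rose 11.7-fold (3.55, SE 0.593, adjusted p = 2.00e-06) and piR-34736 9.18-fold (3.20, SE 0.689, adjusted p = 0.000104). Many piRNA references in such databases share sequence with tRNA and other abundant RNAs, so these names say where reads were counted, not that the RNA is a piRNA. In mouse 4 of 15 rose and 0 fell, with 4 at an unadjusted p under 0.05; mmu_piR_032974 had a log2 fold change of 1.65 (SE 0.435, adjusted p = 0.00407) and mmu_piR_000935 of 1.18 (SE 0.343, adjusted p = 0.00659), and scaled within piRNA 2 rose. Of 86 human circRNA references tested, out of 6761 with reads, 4 rose and 1 fell, or 1 and 2 when scaled by the miRNA library, and the tested ones held 34.5% of circRNA reads. A pair of the 4 that rose had equal counts in 10 of 10 controls and 4 of 10 trauma libraries, so at least part of their reads may be the same.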

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

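Tests of depth, haemolysis, red cell miRNAs and the split within the trauma group, and the counts over other splits of the samples, were chosen only after the results were seen; the tests of summed let-7 reads, of scaling within piRNA and of tRNA-Glu were written down before their results.

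The human smooth muscle and fibroblast list was higher in trauma, with a median log2 fold change of 3.50, though its adjusted p was 0.123 with an estimated correlation. Depth is argued against as the whole cause: with every library thinned to the smallest total the median was 2.836 and 8 of 8 members passed. A smaller share of red cell miRNAs, which would raise all other miRNAs alike, is argued against by the list standing 3.068 above the other miRNAs with the red cell list removed. A difference in haemolysis is argued against as the whole cause. In trauma libraries 6, 7 and 8, whose index (7.68 to 9.42) was no lower than that of the lowest control, the median over controls was 2.399, and the mean of the list was 8.94 ± 0.193 against 5.95 ± 0.887 log2 CPM (n = 3 and 10, exact permutation p = 0.00350). That p is the lowest possible over 286 splits. The list had been singled out in a comparison that included these libraries, so the p is not separate support beside the fold. There 3 of 8 members passed singly, under the 5 first asked for. That bound was judged too strict for 3 libraries, and the permutation p was put in its place, only after the values were seen. Part of the size stays open: with the index as a covariate the median was 2.351 (median SE 0.526, against 0.534 without it) and 4 of 8 members passed, because the fold itself shrank and not because its error grew, and the index contains miR-23a-3p, which rose with trauma. In the other 6 trauma libraries of the split the median was 3.907, and red cell miRNAs took 2.11% to 22.6% of reads, against 47.8% to 62.4% in libraries 6 to 9 and 50.4% to 74.0% in controls. With 101 miRNAs apart between these sets, library or handling batches cannot be told apart from differences between patients or injuries, because the labels give neither. Release of RNA from injured vessel wall or connective tissue may add to what remains, an untested hypothesis, and 1 of the 8 members, miR-145-5p, is also in the TLR ligand list. A high median was not particular to this list. It was 3.73 in the epithelium list, where 3 of 5 members rose, and 3.76 in the brain list, where 2 of 4 rose. The other human lists had lower medians.

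The mouse let-7 family was higher in polytrauma, with a median of 1.88, though its adjusted p was 0.392 with an estimated correlation. Depth is argued against by a median of 1.892 after thinning, with 7 of 9 members passing. Reads moved between family members are argued against by the summed reads of the 9 features, which were higher by 2.155 (SE 0.277, 95% interval 1.581 to 2.728). Haemolysis cannot be told apart. With the index as a covariate the median was 1.751 and 6 of 9 passed, but the index contains miR-23a-3p, which rose (1.35). With miR-451a itself as the covariate the median was 1.797 and 0 of 9 passed. The median SE grew from 0.313 to 0.586. The median fold changed little, but the highest of the members fell from 3.231 to 2.471 and the lowest from 0.4368 to −0.1914. A rise of circulating let-7 after polytrauma is a hypothesis that stays untested beside it, and handling or library batches could not be examined.

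Human piR-33043 was lower in trauma, with a log2 fold change of −5.10. Scaling by the miRNA library is argued against by a value of −6.168 (SE 0.933, adjusted p = 3.41e-06) when scaled within piRNA. Whether its reads are fragments of tRNA-Glu cannot be told apart. Its level and that of tRNA-Glu had Pearson's r = 0.0671 in controls (permutation p = 0.850, rho 0.139, permutation p = 0.709; 95% interval −0.587 to 0.669) and 0.711 in trauma (permutation p = 0.0206, adjusted p = 0.0823 over 4 relations; rho 0.709, permutation p = 0.0275), n = 10 each, and without the 2 libraries farthest from the median r was 0.518 and 0.324. The r in controls lies under the bound of 0.2 set in advance as evidence against; its interval still includes the 0.6 that the explanation needs, so that bound was too weak for 10 libraries, a judgement made after seeing it.

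Chance as the source of the calls was examined with 100 splits per result, the real one included. It was made unlikely for human miRNAs (70 calls, at most 34 in another split, 1 split as large), mouse miRNAs (120, at most 61, 1 split) and differences between species (46, at most 0, 1 split). The same held for human tRNA (4, at most 2, 1 split), mouse tRNA (12, at most 3, 1 split), human piRNA (9, at most 2, 1 split), mouse piRNA (4, at most 2, 1 split) and human circRNA (5, at most 1, 1 split). With 100 splits, chance is not excluded for any of these. For the number of lists passing camera, chance was not even made unlikely. There 11 of 100 splits gave as many as the 4 human lists, with at most 9, and 50 of 100 as many as the 1 mouse list, with at most 6.

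Single libraries stood far from the rest of their group in 14 of 144 groups of values examined. Chance gives about 1 in 20 for independent, normally distributed values. Percent shares and values at the floor need not be normal, and several flags came from the same library, so that rate is only a rough guide. On the log2 CPM scale, miR-30a-5p was 7.511 in human control library 9 (others 9.352 to 10.47) and miR-125a-5p 11.71 in human trauma library 6 (others 13.91 to 16.15). miR-6803-3p was −1.499, the value for no reads, in human control library 8 (others 2.811 to 6.62). In mouse, let-7d-5p was 2.269 in sham library 2 (others 4.336 to 5.351), miR-877-5p 5.742 in polytrauma library 1 (others 3.647 to 4.686), miR-23a-3p 11.94 in sham library 3 (others 11.14 to 11.24) and miR-122-5p 16.73 in polytrauma library 3 (others 12.18 to 13.36). The tRNA share was 12.04% in human control library 8 (others up to 6.052%) and 2.814% in human trauma library 9 (others up to 0.7567%). The piRNA share was 1.07% in mouse polytrauma library 1 (others up to 0.5323%) and 0.4211% in sham library 3 (others up to 0.2215%), and the circRNA share 0.7678% in human control library 8 (others up to 0.3404%). Human trauma library 9 also had the fewest reads of its group on the log10 scale, 6.121 for mature miRNA (others 6.727 to 7.138) and 3.396 for piRNA (others 4.164 to 5.027).

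Of the miRNAs named for the comparison of species, 10 had an effect that differed between species by the interaction test. The rule had named 4 of them for the lowest interaction p and 6 for opposite calls in these same data. Their passing was therefore fixed or nearly fixed by the choice and is no separate support. Some miRNAs named for other reasons passed the test too. The mouse effect minus the human effect was −3.594 for miR-125a-5p, −6.613 for miR-214-3p, −3.002 for miR-125b-5p, −3.418 for miR-29b-3p, 3.127 for miR-215-5p and −1.883 for miR-10b-5p, all 6 called in opposite directions. It was −4.764 for miR-199a-3p/miR-199b-3p, −4.527 for miR-143-3p, −3.483 for miR-224-5p and −7.149 for miR-132-3p. The size for miR-214-3p is uncertain, because some human control libraries had no reads of it.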

How the results depend on the processing

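The fits on libraries of 3000000 to 9000000 reads, those with trauma libraries 6 to 9 or the other 6 alone, and the depth covariate and leave-one-out fits for lists, were chosen after seeing the data. Outside leave-one-out, 100 of 150 values of the 36 results that answer a comparison were kept, and so were 191 of 200 leave-one-out values. A count was taken as kept if it stayed within 1.5-fold of the main count. Outside leave-one-out, 55 counts were kept by that rule and 36 moved. For all other values, kept means the same direction and side of the threshold. Of 1838 values of named miRNAs 1631 were kept, 183 lost the call, 24 gained one and 0 called values changed sign. Values called in neither setting that changed sign, 99 of them and 79 in leave-one-out, were counted as kept. miR-451a and miR-23a-3p were not refitted with the index they define. Causes were not tested except where stated.

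Human miRNAs higher in trauma (54) became 349 with no low-count filter, 31 at a minimum count of 50, 34 on thinning, 10 with the haemolysis covariate and 29 with the depth covariate. Those lower (16) became 36 with DESeq2 (60 higher), 66 with no filter, 25 at a minimum of 50, 28 on thinning, 8 with either covariate, and 9 in libraries of 3000000 to 9000000 reads (5 controls, 6 trauma). With trauma libraries 6 to 9 alone, 8 were higher and 2 lower; with the other 6 alone, 73 and 41. Filters and thinning change which features are tested. Mouse miRNAs higher (65) became 36 with the depth covariate; those lower (55) became 96 with no filter, 34 with the haemolysis covariate, 34 with the depth covariate and 34 against a fold of 1.5. RLE, upper-quartile and DESeq2 scaling moved the human median of all miRNAs by −0.16, −0.17 and −0.16; total count and upper-quartile scaling moved the mouse median by −0.17 and −0.12. Scaled by the miRNA library, human tRNA had 0 higher and 6 lower, mouse tRNA 2 and 18, and human circRNA 1 and 2; within piRNA, mouse had 2 higher. On thinning, 7 miRNAs were called the same way in both species, against 12.

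Adjusted p for lists was lost with the estimated correlation in all 5: 0.123 for brain, 0.495 for endothelium, 0.495 for red cell and 0.123 for smooth muscle and fibroblast in human, 0.392 for let-7 in mouse, which left 0 human and 0 mouse lists. Brain was at 0.639 on thinning, endothelium at 0.0518 under total counts, 0.165 with the haemolysis covariate and 0.112 in libraries of 3000000 to 9000000 reads, red cell at 0.789 with the haemolysis covariate. With trauma libraries 6 to 9 alone 2 human lists passed, endothelium being at 0.181 and red cell at 0.713; with the other 6 alone brain and endothelium were both at 0.0666. In all, 2 human lists passed with the haemolysis covariate and 2 mouse lists with the depth covariate. Leaving out 1 library gave 50 to 68 human miRNAs higher and 11 to 19 lower, 2 to 5 human lists, and adjusted p of 0.00759 to 0.0502 for brain, 0.0261 to 0.0885 for endothelium, 0.000375 to 0.00864 for red cell and 1.15e-06 to 0.000188 for smooth muscle and fibroblast. In mouse it gave 57 to 70 higher, 43 to 60 lower, 1 to 3 lists and 8.37e-06 to 0.000199 for let-7. Human lists fell to 2 without trauma library 9; mouse lists rose to 3 without sham library 1 and to 2 without sham library 3 or polytrauma library 4.

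Replicate numbers shared between groups did not pair the samples: same-numbered deviations correlated at −0.171 to 0.167 in human (1 of 10 over 0.1; 1 correlated best with its own number) and −0.228 to 0.086 in mouse (0 of 6; 1). With the replicate block, 63 human miRNAs were higher and 9 lower, and 40 mouse miRNAs higher and 32 lower, the mouse fit using replicates 1 to 6, which without the block gave 52 and 41. Depth limits the low-abundance miRNAs most, and the human groups differ in it.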

Other observations

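The miRNAs of the first 2 paragraphs, unless named earlier, were chosen after the values were seen; the test of GC content was written down before its result.

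Further human miRNAs were called without any test of the clusters or families they belong to. miR-424-5p (log2 fold change 3.47), miR-503-5p (1.51), miR-542-3p (4.68), miR-450a-5p (2.97) and miR-450b-5p (2.92) rose by the edgeR test (n = 10 and 10), while miR-424-3p did not (0.62, adjusted p = 0.607). Beside miR-23a-3p, miR-27a-3p (1.71, adjusted p = 0.000288), miR-27b-3p (2.27) and miR-24-3p (1.74) rose, while miR-23b-3p stood at −0.02 (adjusted p = 0.993). miR-195-5p rose as well (4.62). Among miR-29 members, which target collagen transcripts, miR-29a-3p (2.34) and miR-29b-3p (2.28) rose and miR-29c-3p did not pass (1.94, adjusted p = 0.0874). miR-320c (−1.61) fell with miR-320b.

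In mouse plasma, miR-26a-5p (1.77) and miR-26b-5p (2.03), and miR-103-3p (2.67) and miR-107-3p (3.03), rose beside let-7 (n = 6 and 9, edgeR test). miR-194-5p (1.98) and miR-215-3p (2.05) rose with miR-192-5p and miR-215-5p. miR-214-3p (−1.71), miR-92b-3p (−1.58) and miR-139-5p (−0.77) fell.

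Several human miRNAs that fell come from GC-rich hairpins, which raised the hypothesis that the effect follows GC content, as a bias of extraction or amplification would. Over 342 of 348 tested features with a hairpin in the annotation, median GC content was 58.9% in the 16 lower (SD 11.7), 51.2% in the 54 higher (SD 8.99) and 52.4% in the others. Spearman's rho between GC content and log2 fold change, across miRNAs that are not independent replicates, was −0.1888, and 100000 splits of the samples gave p = 0.139 for the difference of mean log2 CPM. For the GC content of the hairpin, a relation as strong as the −0.3 set in advance is argued against. The bootstrap 95% interval over libraries was −0.241 to −0.0942, or −0.281 to −0.134 when reflected about the estimate. The p meets a condition written in advance as evidence against, while the rho itself did not meet the alternative condition. Both intervals lie wholly on the negative side, so the p is no evidence against a weaker negative relation. The GC content of the mature miRNA, the part sequenced, could not be examined. The test therefore cannot decide on a bias of extraction or amplification that acts on the mature miRNA. The interval was added after the value was seen, and a weaker relation stays open.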
